A study of Homo sapiens with 6 samples.

How the data were processed

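RNA was measured by strand-specific, paired-end Illumina sequencing in 6 libraries of HK2 cells, an immortalized line of human kidney proximal tubule epithelium. Per the labels, 3 libraries came from cells transfected, with a cationic lipid reagent, with a plasmid that overexpresses NR3C2 (NR3C2-OE), and 3 were controls. NR3C2 encodes the mineralocorticoid receptor. The labels do not say what the control cells received, how long after transfection RNA was taken, or whether a receptor ligand was added. They number the libraries 1 to 3 in both groups and do not say whether these came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

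Adapters were trimmed with cutadapt 1.2.1, per the submitters' processing notes. The aligner, the counting program, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The authors deposited 1 table of 37202 genes with 2 values per library. One is an FPKM value (fragments per kilobase of transcript, scaled to the library size), per the file headers, and the other is an estimated count deposited by the authors as whole numbers. The estimated counts were not tallies of single reads. Among their low values, 4, 8, 12, 16 and 20 were each more frequent than their neighbours, with 8694 values of 4 against 5772 of 3 and 5504 of 5. At 4 counts per read pair, the totals of the libraries would stand for fewer read pairs by that factor, so they overstate the number of independent fragments. Because such estimates depend on how reads are shared among transcripts, the FPKM and the estimated count of a gene with several transcripts can change by different amounts. All 36466 Ensembl identifiers of the table matched the symbol table used here, and 736 further genes that carried only a name given during assembly held 2.88% to 2.98% of the counts and were kept in the library totals and in the tests. No column of values per sample was left unmapped.

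The estimated counts totalled 91956680, 94143458 and 132533971 in Control libraries 1, 2 and 3, and 80032138, 77737375 and 90395149 in NR3C2-OE libraries 1, 2 and 3. Set against counting noise alone, the chi-square per degree of freedom was 57.7 or more for every pair of libraries. Estimated counts that overstate independent fragments inflate this value for any pair, so it does not show that the libraries came from separate cultures. Each library was counted once because the labels give each as a separate sample.

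The counts, already whole, were tested with the quasi-likelihood functions glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, after filterByExpr with its default settings and TMM scaling. The model held the group alone. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05, and all p-values are two-sided. Fold changes are log2 values of NR3C2-OE over Control, and standard errors were derived from the F statistics. The 95% intervals use these errors and 4 residual degrees of freedom. Levels are given as FPKM, mean ± SD over 3 libraries.

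Before the data were examined, 34 gene lists were fixed from textbook knowledge of the kidney tubule, of steroid receptors and of common cell states, with markers of other cell types among them. The 33 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with its preset correlation of 0.01 between the genes of a list, and again with an estimated correlation and with fry. Counts of genes in a list are given after adjustment over all genes tested and adjusted over the list alone. The rule for named genes, fixed at the same time, took NR3C2, every called gene with a symbol whose groups did not overlap and whose mean reached 1 FPKM in the higher group (up to 10 per direction by fold change and 3 by p), 8 receptor-related genes (SGK1, FKBP5, TSC22D3, PER1, SCNN1A, KLF9, NR3C1 and HSD11B2), and up to 4 genes with the smallest p of each list described. Some genes that the rule selected are not reported here. Where other genes are named, this is stated.

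The alternatives fixed before the data were examined were leaving out each library, the replicate number as a block, size factors of DESeq2 1.42.0 in place of TMM, no filter and a filter of 50 counts in 3 libraries, the DESeq2 Wald test, limma-voom, limma-trend on log2(FPKM + 1), a minimum log2 change of 1, and scaling without NR3C2 and genes above 1% of the total. Counts divided by 4, a robust prior in edgeR, thinning to the smallest library, camera on log2(FPKM + 1) and removal of trends on GC content and transcript length were added after seeing the data. GC content and length came from the longest GENCODE 29 transcript and were known for 91.9% of the tested genes. The same annotation was used to find overlapping genes, without printing positions.

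The edgeR steps were tested on data simulated for NR3C2-OE against Control with the means, library sizes and dispersions of the 21509 tested genes. Of 50 genes given each log2 change, the test recovered 0 at 0.25, 1 at 0.5, 19 at 1 and 33 at 2, with 6 false calls among unchanged genes. In 10 simulations that shifted the hypoxia and glycolysis list by 0.15 on the log2 scale, camera with the preset correlation found it 9 times and called 0 other lists, camera with an estimated correlation found it 0 times, and fry 3 times. The simulated genes were drawn independently of each other, which favours the preset correlation. In the real data, the estimated correlation of the 8 lists called by camera ran from -0.027 (WNT and YAP targets) to 0.58 (mitochondrially encoded mRNAs). The simulations therefore do not decide which setting suits the real lists.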

Results

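The series asks which genes respond to the mineralocorticoid receptor NR3C2 in HK2 cells, a human proximal tubule epithelial line. Total RNA of 3 Control libraries and 3 libraries from cells transfected with an NR3C2 plasmid (NR3C2-OE) was sequenced. Estimated counts per library ran from 77737375 to 132533971, and 28440 to 30785 genes had a count above 0. After filtering, 21509 genes were tested. The 10 most abundant genes held 7.29% to 7.64% of the counts of each library. Libraries of the same group were about as alike (Pearson correlation of log2 CPM across genes 0.978 to 0.982) as libraries of different groups (0.978 to 0.981).

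NR3C2 itself (ENSG00000151623), the gene carried by the plasmid, had a higher level in each NR3C2-OE library than in any Control library, by a modest amount. The values do not separate transcripts of the plasmid from those of the cells' own gene, since the plasmid sequence was not used here. Its FPKM was 5.97, 6.26 and 5.16 in the Control libraries and 12.1, 6.95 and 7.41 in the NR3C2-OE libraries, which gave 5.80 ± 0.57 against 8.83 ± 2.86 (SD, n = 3 each). The log2 fold change of 0.68 (SE 0.23) did not pass the edgeR test (adjusted p = 0.486). NR3C2-OE library 1 accounted for much of it, since the log2 fold change was 0.36 without that library.

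Genes known to be induced by mineralocorticoid and glucocorticoid receptors had positive log2 fold changes in 13 and negative ones in 13 of 26 measured genes. SGK1, the kinase that raises sodium channel activity in the tubule, had 64.2 ± 0.41 FPKM in Control and 56.3 ± 1.21 in NR3C2-OE (log2 fold change -0.23, SE 0.038). TSC22D3, which encodes the leucine zipper protein GILZ, had 16.7 ± 2.60 and 23.7 ± 1.38 FPKM (log2 fold change 0.46, SE 0.11). FKBP5, an immunophilin of the receptor complex, had 8.45 ± 0.22 and 8.60 ± 0.48 FPKM, with a log2 fold change of 0.0044 and a 95% interval from -0.16 to 0.17. The log2 fold changes of the clock gene PER1, the epithelial sodium channel subunit SCNN1A and the transcription factor KLF9 were 0.08, 0.14 and 0.23, with standard errors of 0.12, 0.19 and 0.18, and the FPKM of SCNN1A was 0.57 ± 0.13 in Control and 0.47 ± 0.094 in NR3C2-OE. The glucocorticoid receptor NR3C1 (log2 fold change -0.04) and the cortisol-inactivating enzyme HSD11B2 (-0.03) differed by less than the spread between libraries. In edgeR's test, 0 of the 26 measured genes of the receptor target list passed over all genes (7 had an unadjusted p below 0.05, and DESeq2 called 6), while 1 was higher (TSC22D3) and 5 were lower adjusted over the list alone. Among the lower genes were the phosphatase gene DUSP1 (-0.44), endothelin 1 (EDN1, -0.78), SGK1 and the stress gene GADD45A (-0.39). The list as a whole did not pass camera (adjusted p = 0.307, and adjusted p = 0.470 with an estimated correlation), while fry, which does not compare a list with other genes, called it in the downward direction (adjusted p = 0.0281).

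**Figure D1:**
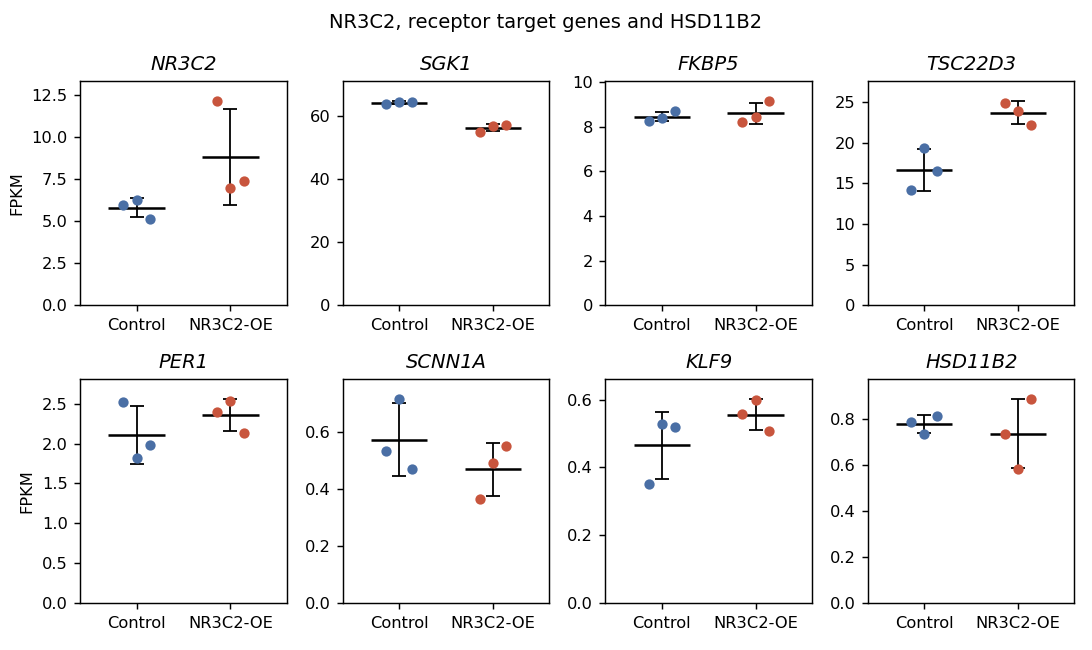
FPKM of NR3C2, of receptor target genes and of HSD11B2 in each library (points), with the mean (line) and SD (bar) of 3 libraries per group. NR3C2 lay at 5.16 to 6.26 FPKM in Control and at 6.95 to 12.1 in NR3C2-OE, while SGK1 was lower in NR3C2-OE (56.3 against 64.2).

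Of the 21509 genes, 6 passed the edgeR test, 3 raised and 3 lowered in NR3C2-OE. BLOC1S2 (ENSG00000196072), a subunit of complexes that position lysosomes and form related organelles, rose from 6.86 ± 0.62 to 16.3 ± 0.62 FPKM (log2 fold change 1.29, SE 0.073, adjusted p = 0.0102). CTDSPL (ENSG00000144677), a phosphatase that acts on the retinoblastoma protein, rose from 4.29 ± 0.49 to 10.1 ± 0.71 FPKM. Its estimated counts rose more than its FPKM, 4.34-fold against 2.34-fold (log2 fold change 2.12, SE 0.12, adjusted p = 0.0102). CHMP1A (ENSG00000131165), a component of the ESCRT-III membrane-remodelling machinery, rose from 15.4 ± 1.08 to 40.2 ± 3.81 FPKM (log2 fold change 0.93, SE 0.077, adjusted p = 0.0476). PTGES3 (ENSG00000110958), the HSP90 co-chaperone p23 that stabilizes steroid receptors in their ligand-binding form, fell from 198 ± 7.58 to 111 ± 8.92 FPKM (log2 fold change -0.91, SE 0.067, adjusted p = 0.0319). DRAM1 (ENSG00000136048), a lysosomal membrane protein that promotes autophagy, fell from 43.0 ± 1.3 to 21.3 ± 2.05 FPKM (log2 fold change -1.26, SE 0.095, adjusted p = 0.0319). The zinc finger gene ZNF7 (ENSG00000147789) fell from 6.06 ± 0.65 to 3.37 ± 0.20 FPKM (log2 fold change -1.58, SE 0.092, adjusted p = 0.0102). ZNF7 overlaps COMMD5 in the reference annotation, and with the counts of both added the log2 change was -0.65. COMMD5 had a mean of 14.3 CPM in Control and 16.6 in NR3C2-OE, so adding it shrinks the log2 change even without moved reads. Without adjustment, 1976 genes had an edgeR p below 0.05 (953 higher and 1023 lower). The groups did not overlap in 16.7% of tested genes, where 10% is the chance for a single gene. Genes vary together, so the share in a single division can lie away from 10%. It was not computed for other divisions, and 16.7% is not evidence of an excess. The DESeq2 Wald test called 250 genes (103 raised and 147 lowered, all 6 above among them). It also called 50 to 89 genes in the 9 other divisions of the 6 libraries into 3 and 3, so its single calls carry less weight. When 1 library was left out, the call held in all 6 fits for BLOC1S2, in 5 for CTDSPL and ZNF7 (lost without Control library 1, edgeR adjusted p = 0.0523), in 2 for PTGES3 (without NR3C2-OE library 1 or 2) and DRAM1 (without NR3C2-OE library 2 or 3), with edgeR adjusted p up to 0.0965, and in 1 for CHMP1A (without NR3C2-OE library 3), with edgeR adjusted p up to 0.132. The edgeR count was 13, 14, 18 and 16 without Control library 2 and NR3C2-OE libraries 1, 2 and 3, and 5 raised and 0 lowered without Control library 1, and the 9 other divisions of the 6 libraries into 3 and 3 gave 2 to 13 genes.

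**Figure D2:**
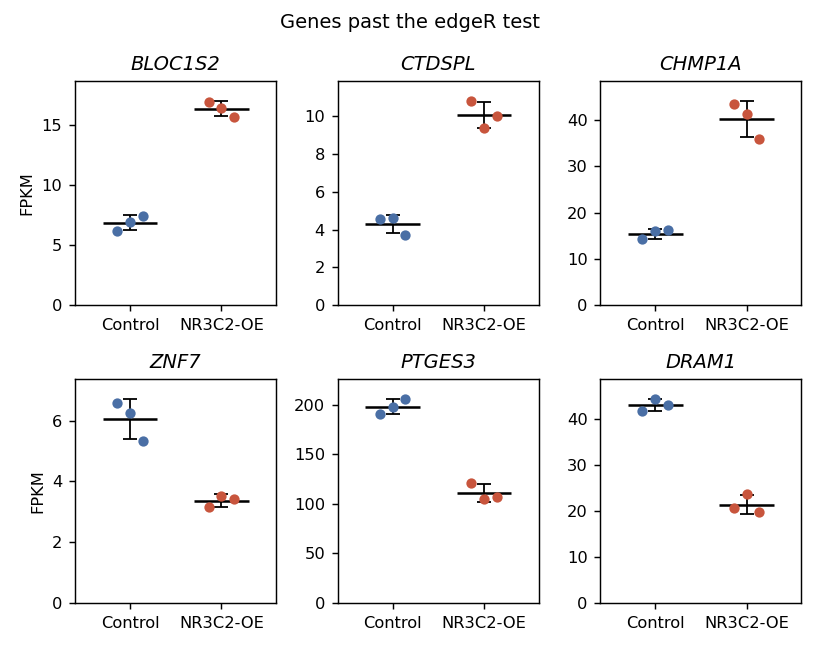
FPKM of the 6 genes that passed the edgeR test in each library (points), with the mean (line) and SD (bar) of 3 libraries per group. In each panel the 3 NR3C2-OE libraries lie apart from the 3 Control libraries, for example at a mean of 111 against 198 FPKM for PTGES3.

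Of the 33 gene lists tested, 8 passed camera with its preset correlation, 3 in the upward and 5 in the downward direction. With an estimated correlation 0 lists passed (p = 0.0252 or more before adjustment for each of the 8, and adjusted p = 0.251 or more), and fry called 7. Of these 7, 5 were among the 8, and the others were the receptor targets and the inflammatory cytokine list. Fry did not call mitochondrially encoded mRNAs (adjusted p = 0.0718), TGF-beta genes (0.0718) or autophagy genes (0.115). Camera called 5 lists without the filter on low counts and 4 without NR3C2-OE library 2.

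Genes of the cell cycle list parted by phase, although the list was not divided by phase when it was fixed. Of its 37 measured genes, 0 passed over all genes in edgeR's test (30 had an unadjusted p below 0.05, and DESeq2 called 2 higher and 10 lower), while 11 were higher and 19 lower in NR3C2-OE adjusted over the list alone. The higher genes act at the start of DNA replication. They comprised the replicative helicase subunits MCM2 to MCM7, the licensing factors CDT1 and CDC6, cyclin E1 (CCNE1), E2F1 and PCNA. MCM6 had 53.5 ± 0.74 FPKM in Control and 66.2 ± 1.21 in NR3C2-OE (log2 fold change 0.29, SE 0.041). The lower genes act in G2 and mitosis. Among them were cyclin A2 (CCNA2, 71.3 ± 1.2 and 59.8 ± 1.28 FPKM, log2 fold change -0.28, SE 0.037), the spindle factor TPX2 (-0.28, SE 0.040) and the mitotic ubiquitin-conjugating enzyme UBE2C (204 ± 8.07 and 162 ± 8.67 FPKM, log2 fold change -0.36, SE 0.052). TOP2A, CCNB1, PLK1, AURKA and MKI67, like the higher genes other than MCM6, were named after their values were seen, and the log2 fold change of AURKA was -0.62 (SE 0.17). The list passed camera in the downward direction (adjusted p = 0.0496, and adjusted p = 0.315 with an estimated correlation). This call was lost without any 1 of the 6 libraries (adjusted p 0.0607 to 0.133). Its direction does not describe the list as a whole. Log2 fold changes were positive in 14 of 15 G1/S genes and negative in 21 of 22 G2/M genes.

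**Figure D3:**
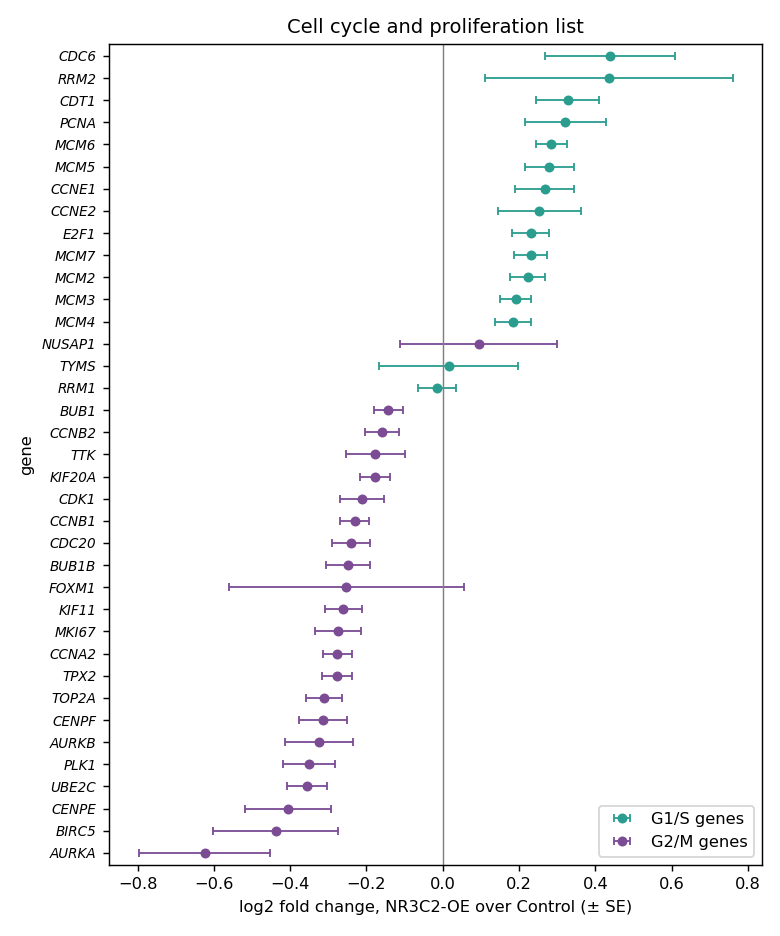
Log2 fold change of NR3C2-OE over Control (x axis) with its standard error (bars) for the 37 genes of the cell cycle list (y axis), from edgeR. Genes of G1/S lie mainly above 0, such as MCM6 at 0.29, and genes of G2/M mainly below, such as UBE2C at -0.36.

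Transcripts of the mitochondrial genome and of heat shock chaperones were lower in NR3C2-OE as groups. All 13 mitochondrially encoded mRNAs had negative log2 fold changes, with a median of -0.25, and 9 of them were lower adjusted over the list alone in edgeR's test, while 0 passed over all genes (9 had an unadjusted p below 0.05, and DESeq2 called 2). MT-ND1 had 1067 ± 61.6 FPKM in Control and 868 ± 33.4 in NR3C2-OE, and MT-CO1 had 6258 ± 150 and 5651 ± 129. The log2 fold changes of MT-ND5 and MT-CYB were -0.31 (SE 0.062) and -0.22 (SE 0.054). Mitochondrial genes held 3.91%, 4.10% and 4.04% of the counts of the Control libraries and 3.74%, 3.49% and 3.48% of the NR3C2-OE libraries. The 34 nuclear genes of the respiratory chain did not differ as a list (camera adjusted p = 0.591, and adjusted p = 0.787 with an estimated correlation). In the heat shock list, 17 of 20 genes had negative log2 fold changes, and 6 were lower adjusted over the list alone, with 0 over all genes (10 had an unadjusted p below 0.05, and DESeq2 called 2). The constitutive chaperone HSPA8 had 988 ± 120 and 624 ± 114 FPKM (log2 fold change -0.48, SE 0.080). The HSP90 genes HSP90AB1 (732 ± 17.5 and 647 ± 13.3 FPKM) and HSP90AA1 (427 ± 4.45 and 380 ± 11.1 FPKM) had log2 fold changes of -0.20 and -0.19, and the small heat shock protein CRYAB -0.27. In limma's camera test, the adjusted p was 5.5e-07 for mitochondrial mRNAs and 2.3e-06 for heat shock genes. With an estimated correlation the adjusted p was 0.318 and 0.251, and neither list passed.

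HSP90AA1, HSP90AB1 and PTGES3 also belong to the list of steroid receptors and cofactors. Of its 18 measured genes, 1 fell over all genes (PTGES3), and 1 was higher and 3 were lower adjusted over the list alone. The coactivator NCOA3 had 15.8 ± 0.16 FPKM in Control and 17.7 ± 0.42 in NR3C2-OE (log2 fold change 0.15, SE 0.043). The list did not pass camera (adjusted p = 0.0743, and adjusted p = 0.318 with an estimated correlation).

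Genes of glycolysis and hypoxia and of the amino acid response were higher in NR3C2-OE as groups, and genes of autophagy passed the same test narrowly. In the hypoxia and glycolysis list, 27 of 31 measured genes had positive log2 fold changes (median 0.12), and 7 were higher adjusted over the list alone, with 0 over all genes in edgeR's test (11 had an unadjusted p below 0.05, and DESeq2 called 2). They included the glycolytic enzymes GPI (log2 fold change 0.46, SE 0.052, in the counts, with overlapping FPKM of 75.4 ± 22.2 and 83.5 ± 5.05) and PFKL (0.23, SE 0.057), the glucose transporter SLC2A3 (0.31, SE 0.076) and the hypoxia-inducible gene NDRG1 (13.1 ± 2.15 and 21.8 ± 1.89 FPKM, log2 fold change 0.63, SE 0.14). In the amino acid and integrated stress response list, 20 of 26 genes had positive log2 fold changes, and 5 were higher adjusted over the list alone, with 0 over all genes (9 had an unadjusted p below 0.05, and DESeq2 called 3). Among them were DDIT4, an inhibitor of mTORC1 (14.2 ± 0.42 and 19.8 ± 2.06 FPKM, log2 fold change 0.44, SE 0.085), the serine synthesis enzyme PSPH (0.38, SE 0.068), the cysteinyl-tRNA synthetase CARS1 (0.34, SE 0.058) and the stress cytokine GDF15 (46.2 ± 0.27 and 59.2 ± 6.16 FPKM). In the autophagy and lysosome list, 18 of 25 genes had positive log2 fold changes and 0 passed edgeR's test by either adjustment (3 had an unadjusted p below 0.05, and DESeq2 called 0). The smallest p-values belonged to NPC1 (log2 fold change 0.20), ULK1 (0.21), ATG5 (0.46) and LAMP2 (0.10). Camera gave an adjusted p of 5.4e-06 for hypoxia and glycolysis, 0.00075 for the amino acid response and 0.0488 for autophagy, and with an estimated correlation an adjusted p of 0.251, 0.251 and 0.318. The autophagy call held in 2 of the 6 fits that left out 1 library (adjusted p 0.0195 to 0.231), and it was lost without the filter on low counts (0.148), on log2(FPKM + 1) (0.0813) and with fry (0.115).

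**Figure D4:**
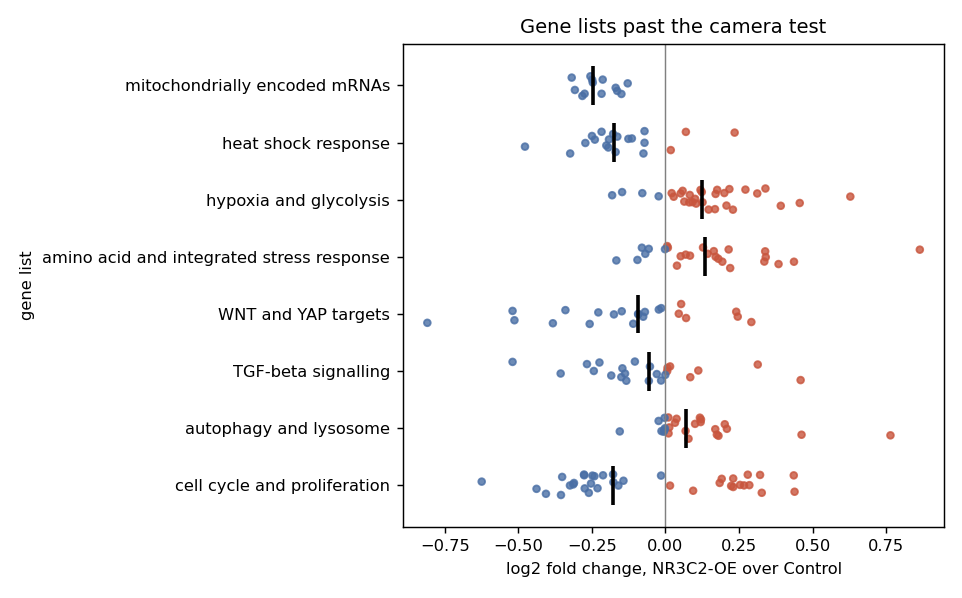
Log2 fold change of NR3C2-OE over Control (x axis) of each gene (points) in the 8 lists that passed camera with its preset correlation (y axis), with the list's median (black line). Points above 0 are red and points at or below 0 are blue, and medians run from -0.25 for mitochondrially encoded mRNAs to 0.14 for the amino acid response.

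A joint list of WNT and YAP targets was lower in NR3C2-OE as a group, and genes of TGF-beta signalling passed the same test narrowly, with CCN2 in both lists. CCN2, the matricellular protein CTGF, had 87.9 ± 4.93 FPKM in Control and 62.3 ± 4.61 in NR3C2-OE (log2 fold change -0.52, SE 0.070). In the WNT and YAP list, 16 of 22 genes had negative log2 fold changes, among them cyclin D1 (CCND1, -0.23), CRIM1 (-0.15) and ANKRD1 (-0.26), and only CCN2 was lower adjusted over the list alone, with 0 over all genes in edgeR's test (6 had an unadjusted p below 0.05, and DESeq2 called 1). In the TGF-beta list, 16 of 23 genes had negative log2 fold changes, and 3 were lower adjusted over the list alone, CCN2 and ID1 among them, with 0 over all genes (7 had an unadjusted p below 0.05, and DESeq2 called 2). ID1 had 140 ± 1.82 and 125 ± 2.46 FPKM, and the ligand TGFB2 had 38.1 ± 2.47 and 32.1 ± 2.54. Camera gave an adjusted p of 0.0189 for WNT and YAP targets and 0.0407 for TGF-beta genes, and with an estimated correlation an adjusted p of 0.251 and 0.315. The calls held in 4 of 6 (adjusted p 0.0209 to 0.0721) and 1 of 6 (0.0201 to 0.160) fits that left out 1 library, and the TGF-beta call was also lost without the filter on low counts (adjusted p = 0.125), on log2(FPKM + 1) (0.125) and with fry (0.0718). The extracellular matrix list, which shares CCN2, did not pass (camera adjusted p = 0.0665, and adjusted p = 0.463 with an estimated correlation). Of its 25 measured genes, 4 were lower adjusted over the list alone, among them CCN2, thrombospondin 1 (THBS1, -0.33, SE 0.052) and tenascin C (TNC, -0.22, SE 0.049), and 0 passed over all genes in edgeR's test (6 had an unadjusted p below 0.05, and DESeq2 called 3).

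Cytokine and immediate early genes did not pass camera as lists, although single members lay apart. In the list of inflammatory cytokines and NF-kB targets, 3 of 27 genes were lower adjusted over the list alone, with 0 over all genes in edgeR's test (6 had an unadjusted p below 0.05, and DESeq2 called 2). These were IL11 (17.3 ± 1.26 and 11.8 ± 0.80 FPKM, log2 fold change -0.56, SE 0.071), IL6 (271 ± 4.68 and 227 ± 13.3 FPKM) and CXCL2 (-0.25, SE 0.050). Fry called that list in the downward direction (adjusted p = 0.0196). Camera gave it an adjusted p of 0.407, and its median (-0.05) and mean (0.0074) differed in sign. Among 29 immediate early genes, DUSP1 and EGR1 (-0.45, SE 0.084) were lower and JUND (0.33, SE 0.077) was higher adjusted over the list alone, with 0 over all genes (8 had an unadjusted p below 0.05, DESeq2 called 2, and the camera adjusted p was 0.0699). The log2 fold change of FOS was -0.84 (SE 0.22) in the counts, and its FPKM, 0.60 ± 0.069 in Control and 0.47 ± 0.15 in NR3C2-OE, overlapped between the groups. With an estimated correlation both lists had an adjusted p of 0.48.

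Markers of the proximal tubule and of ion transport did not differ as lists. Camera gave an adjusted p of 0.139 for 14 measured proximal tubule markers and 0.134 for 22 sodium and potassium transport genes (adjusted p = 0.482 and 0.333 with an estimated correlation), and 0 genes of either list passed by either adjustment in edgeR's test (1 and 3 had an unadjusted p below 0.05, and DESeq2 called 0). The log2 fold change of the tubule transcription factor PAX8 was 0.12 (SE 0.054), and the cadherin CDH6 had 80.4 ± 2.04 FPKM in Control and 91.4 ± 8.41 in NR3C2-OE. The log2 fold changes of the potassium channel KCNMA1 and the phosphate transporter SLC20A1 were 0.18 and 0.15. The log2 fold change of DPP4 was 0.35 in the estimated counts and -0.05 on the log2(FPKM + 1) scale. Of 7 measured leukocyte markers, CD68 was higher adjusted over the list alone (20.9 ± 0.15 and 27.1 ± 3.37 FPKM, log2 fold change 0.38, SE 0.090), and 0 passed over all genes (1 had an unadjusted p below 0.05, and DESeq2 called 0). CD68 is a lysosomal membrane protein found in many cell types, and the monocyte marker CD14 had 0.28 and 0.34 FPKM. Camera gave an adjusted p of 0.0665 for leukocyte markers, 0.407 for fibroblast and muscle-like markers and 0.775 for distal tubule markers, and with an estimated correlation an adjusted p of 0.318, 0.526 and 0.787. Only 4 endothelial markers were measured, too few for the test.

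The remaining lists gave no call by camera. The adjusted p was 0.0725 for 28 interferon response genes, with positive log2 fold changes in 18, and 0 passed in edgeR's test by either adjustment (3 had an unadjusted p below 0.05, and DESeq2 called 0). IRF9 had 1.82 ± 0.16 FPKM in Control and 2.57 ± 0.14 in NR3C2-OE. The adjusted p was also 0.0725 for 25 cholesterol synthesis genes, with negative log2 fold changes in 18, and 0 of the 25 passed by either adjustment (2 had an unadjusted p below 0.05, and DESeq2 called 0). Among 21 genes of fatty acid synthesis and storage (adjusted p = 0.239), the lipid droplet protein PLIN2 was higher adjusted over the list alone (35.2 ± 1.63 and 46.3 ± 3.31 FPKM, log2 fold change 0.36, SE 0.070). Among 25 p53 targets (adjusted p = 0.575), GADD45A and the kinase PLK2 (-0.19, SE 0.039) were lower adjusted over the list alone. The other lists tested covered ribosomal proteins (adjusted p = 0.212), the unfolded protein response (0.299), metallothioneins (0.413), apoptosis regulators (0.478), fatty acid oxidation (0.575), epithelial to mesenchymal transition (0.643), ferroptosis regulators (0.775), replication-dependent histones (0.775), oxidative stress and NRF2 targets (0.872), and growth factors and ERBB ligands (0.872).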

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

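Counts divided by 4, the robust prior, thinning, camera on FPKM and the removal of GC and length trends were chosen after seeing the data. Of 1582 values of the 89 named genes under alternatives, 1569 kept their direction. Most of these genes were named for small p-values in the same libraries that the alternatives refit. A high share was therefore likely and is not evidence that the changes are real. The 6 called genes were called again, as the same genes, with DESeq2 size factors, without a filter, with the stricter filter, with scaling without abundant genes, with counts divided by 4, after thinning (6 genes each) and with the robust prior (9 genes, 5 raised and 4 lowered). Limma-voom called 5 genes, all among the 6, a minimum log2 change of 1 left 4, and limma-trend on log2(FPKM + 1) called 9 (5 raised and 4 lowered, 5 shared). The DESeq2 Wald test called 250 genes, 103 raised and 147 lowered. Leaving out 1 library gave 5 to 18 changed genes, 4 to 8 raised and 0 to 10 lowered. BLOC1S2 was called in all 6 of these fits, CTDSPL and ZNF7 in 5 (lost without Control library 1, adjusted p = 0.0523 by edgeR), PTGES3 in 2 (without NR3C2-OE library 1 or 2), DRAM1 in 2 (without NR3C2-OE library 2 or 3) and CHMP1A in 1 (without NR3C2-OE library 3), with adjusted p up to 0.132 in the others. The log2 fold change of NR3C2 ran from 0.36 to 0.84 in them.

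With the replicate number as a block, edgeR called 0 genes (0 raised and 0 lowered, with 1490 at an unadjusted p below 0.05), and camera called 5 lists. The deviations of libraries with the same number correlated at 0.027, 0.016 and 0.0038. Control libraries 1 and 2, but not 3, correlated best with the NR3C2-OE library of their own number. No bound was set for these values, so they do not decide whether the numbers mark pairs. Camera called 8 lists as reported, 4 to 7 without 1 library (4 without NR3C2-OE library 2), 7 with size factors, 5 without a filter, 8 with the stricter filter, 8 with counts divided by 4, 8 after thinning, 9 with GC and length trends removed, 6 on log2(FPKM + 1) and 0 with an estimated correlation. Fry called 7, of which 5 were shared. Mitochondrial mRNAs, heat shock, hypoxia and glycolysis, and the amino acid response were called without any 1 library.

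Of the named genes, 5 changed sign under an alternative, 4 of them from values near 0. FKBP5 was at -0.0064 without a filter, -0.00070 by DESeq2 and -0.0011 after thinning, NR3C1 at 0.0080 on FPKM, HSD11B2 at 0.096 after thinning, and DPP4, at 0.35 in the counts (SE 0.083), was at -0.046 on FPKM. Leaving out 1 library gave -0.039 to 0.031 for FKBP5, -0.0011 to 0.16 for PER1, -0.14 to 0.029 for NR3C1 and -0.099 to 0.059 for HSD11B2. The cause of these differences was not tested. Pseudocounts of FPKM other than 1 were not run, since counts were the main unit. In simulations edgeR recovered 38% of genes at a log2 change of 1 and 2% at 0.5, so smaller changes were mostly out of reach of single-gene calls.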

Other observations

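Beyond the fixed lists, the KEGG pathway names that the deposited table attaches to genes were tested with camera over 349 pathways of 10 to 400 tested genes, and 3 passed. Ribosome biogenesis was lower in NR3C2-OE, with negative log2 fold changes in 58 of 82 genes (adjusted p = 0.0078), led by the nucleolar proteins NOP56 (-0.19, SE 0.036, with 168 ± 7.5 and 155 ± 7.3 FPKM) and NOL6 (-0.26, SE 0.057). DNA replication was higher, with positive log2 fold changes in 34 of 46 genes (adjusted p = 0.0078), led by MCM6 (0.29, SE 0.041) and MCM7 (0.23, SE 0.043). Motor proteins were lower as a group, with negative log2 fold changes in 121 of 186 genes (adjusted p = 0.0401). The smallest edgeR p belonged to C9orf64 (-1.02, SE 0.097), followed by the mitotic kinesins KIFC1 (-0.39, SE 0.064), KIF14 (-0.40, SE 0.069) and KIF23 (-0.34, SE 0.061). DNAH14 (-0.45, SE 0.085) and ACTB (-0.36, SE 0.071) were also among the leading members, so the pathway does not stand for mitotic kinesins alone. With an estimated correlation 0 pathways passed (adjusted p = 0.997 for each of these). Pathways near the lists that passed in the report did not pass here, with an adjusted p of 0.992 each for the cell cycle (negative in 98 of 175 genes), glycolysis (positive in 36 of 60), HIF-1 signalling (positive in 56 of 88), oxidative phosphorylation, aminoacyl-tRNA synthesis and WNT, Hippo and TGF-beta signalling, 0.919 for protein processing in the endoplasmic reticulum and 0.185 for animal autophagy (positive in 114 of 172). None of the genes named here passed edgeR's test over all genes.

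Genes of the serum response factor SRF and the actin cytoskeleton, a list chosen after the data were examined, had negative log2 fold changes in 31 of 36 measured members. The KEGG pathway for regulation of the actin cytoskeleton, not chosen on these libraries, had negative ones in 119 of 215 genes and did not pass camera (adjusted p = 0.992). SRF itself had 18.8 ± 0.41 FPKM in Control and 15.2 ± 0.39 in NR3C2-OE (SD, n = 3 each), beta-actin (ACTB) had 1539 ± 92 and 1180 ± 52, and the actin-binding protein NEXN had 26.0 ± 1.0 and 18.4 ± 2.2. In edgeR's test 14 members were lower and 1 was higher adjusted over the list alone, with 0 over all genes (17 had an unadjusted p below 0.05, and DESeq2 called 7 lower and 1 higher). The higher member was tropomyosin 4 (TPM4, log2 fold change 1.03, SE 0.22). Because the list was chosen on these libraries, its camera p of 2.3e-09 (p = 0.0023 with an estimated correlation) is not independent evidence. Of 44 ribosome assembly genes, a list chosen in the same way, 41 had negative log2 fold changes and 8 were lower adjusted over the list alone, with 0 over all genes in edgeR's test (19 had an unadjusted p below 0.05, DESeq2 called 7, and camera gave p = 1.5e-10, and p = 0.012 with an estimated correlation).

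In the weighing of the patterns that follow, the tests of FPKM, of G1/S and G2/M genes outside the fixed list, of growth state, of reassigned reads in parts of the gene set and of swapped labels were chosen after the results were seen. The first pattern is the parting of G1/S genes, higher in NR3C2-OE, from G2/M genes, lower. The mean log2 level of 15 G1/S genes minus that of 22 G2/M genes was -0.45 ± 0.049 in Control and 0.056 ± 0.035 in NR3C2-OE, a difference of 0.51 (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The fixed list did not divide its genes by phase, and the division was added for this pattern. The difference and its p are therefore not a test of a score fixed beforehand. Trends on GC content and transcript length are argued against as its whole source, since the difference was 0.502 with the trends removed. After thinning the difference was 0.507. Thinning hardly moves the expected level of genes with counts this high, so this result decides nothing about library depth. A different mix of cell cycle phases stays a candidate explanation. Its prediction held, since 42 G1/S and 37 G2/M genes outside the fixed list also parted, by 0.271, in all 3 NR3C2-OE against all 3 Control libraries. Any cause that moves the genes of a phase together would give the same parting in these libraries. The result therefore does not single out a phase mix. Whether NR3C2, the transfection itself or a difference in growth state between dishes lay behind the parting cannot be told apart. The labels do not say what the control cells received and record no growth state apart from the group. The pass of both of the 2 growth state lists (actin cytoskeleton and ribosome assembly) decides nothing, because they were chosen on these libraries.

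The second pattern is the set of genes past edgeR's test. A shift of transcript length in the count estimate is argued against as the whole source, since the FPKM of all 6 genes parted in the same direction, although the log2 FPKM ratio was smaller in size than the log2 count change for CTDSPL (1.23 against 2.12) and ZNF7 (-0.85 against -1.58) and larger for CHMP1A (1.38 against 0.93). Reads reassigned to the partners found, overlapping genes or pseudogene copies, are argued against for CTDSPL, DRAM1, PTGES3 and CHMP1A. These genes kept 82.1% or more of their log2 change when the counts of such partners were added (the partners of CTDSPL and DRAM1 held at most 0.080 CPM). Overlaps were sought in the annotation that gave GC content and length for 91.9% of the tested genes. Reads moved to genes outside it, or to the 736 genes named during assembly, could not be seen. For the set, reassigned reads stay open, because the bound set beforehand was 5 of 6 genes keeping over 50%. It was met only by counting BLOC1S2, for which no partner was found and which so was not tested, which leaves 4. ZNF7 kept 40.8%, but adding a partner that barely differs also shrinks a log2 change, so this loss alone decides nothing. The CPM of ZNF7 ran from 22.5 to 25.6 in Control and from 7.69 to 8.84 in NR3C2-OE. Its partner COMMD5 had a mean of 14.3 CPM in Control and 16.6 in NR3C2-OE, and so gained less than ZNF7 lost. By edgeR, 7 of the 10 divisions of the 6 libraries into 3 and 3 gave 6 or more genes (6 for the real one, 13 at most for another). The number of genes past edgeR's test was thus no larger than in most other divisions, the outcome set beforehand for a chance origin. By DESeq2, 1 division gave 250 genes (the real one, against 89 at most for another). By camera, 1 gave 8 lists (the real one, against 5 at most for another). For the DESeq2 and camera counts, 10 divisions are too few for a share below 0.05.

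The third pattern is NR3C2 at a log2 fold change of 0.68 (SE 0.23, adjusted p = 0.486 in edgeR's test, and 0.36 without NR3C2-OE library 1) beside SGK1 at -0.23 and FKBP5 at 0.0044. Another receptor target, TSC22D3, was higher at 0.46 (SE 0.11, edgeR adjusted p = 0.0251 over the list alone and 0.349 over all genes). Labels swapped between the groups cannot be told apart from correct ones here, since the ratio of the lowest NR3C2-OE to the highest Control library, 1.11, restates the pattern and decides nothing. No biological explanation was tested, and the labels name no receptor ligand.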
